A study of Mus musculus with 8 samples.

How the data were processed

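RNA was sequenced from 6 libraries, 3 of the mouse kidney line mK3 and 3 of mK4, and ATAC-seq was done on 1 library of each line. Per the labels, both lines were kept in the same medium with no treatment, total RNA was depleted of ribosomal RNA, and strand-specific libraries were built, with an extra step that removes linear RNA for circular RNA libraries. The labels call the RNA libraries duplicates with a number and do not say whether separate cultures were used.

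The deposited expression table holds whole-number read counts per feature, not normalized, for 59004 features. Of these, 55558 are Ensembl genes with symbol and biotype, 1196 are mature miRNA names and 2250 are circular RNA names. Per the submitters' processing notes, the tools were STAR 2.7.10a, HTSeq 2.0.2, Bowtie2, SAMtools, bedtools, MACS3 and deepTools, with the genome build mm10. Which of them made which values, and how miRNA and circular RNA reads were counted, is not given in the sources used here. The deposited peak lists, 1 per line, give each peak's fold enrichment over background (a ratio) and its -log10 q, both as the authors' peak caller wrote them, per the column order of the format. The peak-calling settings are not given in the sources used here.

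No feature was a total or an unassigned class, and 25379 gene features were at 0 in all 6 libraries. Library totals were 137559391 to 152952351 counts. Replicates of a line correlated at 0.8825 to 0.9073 on the log2 scale over genes and libraries of different lines at 0.7361 to 0.7606. No pair of replicates differed by as little as sampling noise. A total of 34 of 10150 genes in mK3 and 67 of 10565 in mK4 with over 500 counts in a library, protein-coding only, differed over 20-fold between replicates of a line. None of 72 ribosomal protein genes was at 0.

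Genes, miRNAs and circular RNAs were each fitted on their own with edgeR 4.0.16 in R 4.3.3, on the counts as deposited, with filterByExpr, TMM scaling and the robust quasi-likelihood test (glmQLFit and glmQLFTest) of mK4 against mK3. P-values were adjusted by Benjamini and Hochberg within each class, and calls were made at 0.05. CPM were computed within each class after TMM scaling. Where a gene was at 0 in every library of a line, the fold was bounded with a floor of 3 counts per library, and list medians used these bounds. Gene lists were tested with camera in limma 3.58.1, which compares a list with all other genes, with its preset correlation of 0.01, a variance trend and a two-sided p. The 34 lists were fixed before the data were examined, and the 31 with at least 5 tested genes were tested. They cover nephron progenitors, induced mesenchyme and renal vesicle, tubule, epithelial junctions and keratins, mesenchyme and EMT, renal stroma, ureteric bud, podocytes, endothelium, leukocytes, contractile cells, skeletal muscle, neurons and glia, the Wnt, FGF and ERK, Notch, BMP and TGF-beta and Hedgehog pathways, cell cycle, p53 targets, interferon response, antigen presentation, basement membrane, glycolysis, oxidative phosphorylation, cholesterol synthesis, stress responses, mitochondrially encoded, sex chromosome and imprinted genes, and the Hox A, B, C and D clusters.

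Named genes followed a rule set in advance. It took the 10 largest increases and the 10 largest decreases among called genes whose libraries did not overlap, with a mean log2 CPM of at least 3 over the 6 libraries, leaving out predicted, ribosomal, small nuclear and nucleolar RNA and pseudogene features. It added up to 2 members of each list per direction with the smallest adjusted p, 19 kidney and epithelial genes whatever their value, the 5 strongest peaks of each line without a partner, and the peaks at the 19 genes. The comparisons of miRNAs and circular RNAs, gene families and the expression of miRNA host genes were chosen after the data were seen.

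Peaks on chromosomes 1 to 19, X and Y were kept. Peaks of the lines were called overlapping when they shared at least 1 bp, computed in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3 in place of the planned bedtools. Gene coordinates came from the RefSeq table for the assembly GRCm38.p6, which is mm10, and matched 16870 of 20405 tested genes (82.7%). As strand was not used, a gene-end peak is one within 1 kb of either end of a gene. When gene coordinates were moved by 100 kb, 1247 genes in mK3 and 1839 in mK4 had a gene-end peak, against 9147 and 10115 in place. The medians of peak classes were set against 10000 random lists matched on mean expression in 20 bins. Permutation tests used NumPy, and exact binomial tests and intervals used SciPy 1.17.1.

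The steps were tested on simulated data. With 3 libraries per line, the gene test recovered 1.5% of genes changed 1.5-fold, 31.3% of those changed 2-fold and 87.9% of those changed 4-fold, with 7 false calls among 19641 unchanged genes. For miRNAs the shares were 60%, 100% and 100%, with 1 false call of 392, and for circular RNAs 0%, 10% and 33.3%, with 0 of 160. The simulations changed fewer features than were called in the data, and only features above the median level. They left 19641 of 19841 genes and 392 of 452 miRNAs unchanged, against 40.3% of genes and 67.7% of miRNAs called. The shares therefore do not give the power of the comparisons here. The overlap code gave the right answer in 4 of 4 constructed cases. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, each library left out, the replicate number as a block, stricter peaks and other overlap rules.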

Results

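The series compared a pair of mouse kidney cell lines, mK3 and mK4. Both derive from the metanephric mesenchyme, the embryonic tissue that gives rise to the nephrons. The labels describe mK3 as uninduced and mK4 as differentiated towards epithelium, and both lines were grown in the same serum-containing medium. RNA was sequenced from 3 libraries per line, and open chromatin was profiled by ATAC-seq, in which a transposase inserts adapters into accessible DNA, in 1 library per line. The deposited count table held 137559391 to 152952351 counts per RNA library. Ensembl genes took 133899125 to 146187601 of these, mature miRNAs 3191483 to 6755311 and circular RNAs 6725 to 15019. The labels do not say whether the 3 libraries of a line came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Values below are mean CPM, counts scaled to library size, ± SD with n = 3 libraries per line, and floors and intervals cover counting error only.

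The first comparison asked which genes differ in expression between the lines. The matrix glycoprotein gene Thbs2 went from 2764 ± 99.7 CPM in mK3 to 0.081 ± 0.14 CPM in mK4, and Lox, which encodes a collagen cross-linking enzyme, went from 1572 ± 30.4 to 0.179 ± 0.155 CPM. The type I collagen gene Col1a2 went from 981 ± 105 to 0.221 ± 0.114 CPM, and the mesenchymal transcription factor gene Prrx1 from 736 ± 13.7 to 0.19 ± 0.157 CPM. Col8a1, Bgn, Ifi202b, Acta2, Sema3d and Cdh11 completed the 10 largest decreases under the fixed rule, which asks for a mean log2 CPM of at least 3 and so passes over genes at 0 in a line, with log2 fold changes from -10.72 (Col8a1) to -7.74 (Cdh11). In the other direction Pkhd1, which encodes fibrocystin, a protein of renal tubule cilia, rose from 1.19 ± 0.088 CPM in mK3 to 232 ± 5.15 CPM in mK4. Cxadr, which encodes a tight-junction adhesion protein, rose from 5.81 ± 1.85 to 438 ± 19.1 CPM, and the secreted Wnt modulator gene Sfrp1 rose from 1.68 ± 1.48 to 140 ± 4.18 CPM. Mob3b, Emb, Parm1, Baiap2l1, Rorb, Grik5 and Neurl1b were the others of the 10 largest increases, with log2 fold changes from 6.91 (Mob3b) to 5.93 (Neurl1b). The adjusted p of these 20 genes was 0.00185 (Sfrp1) or less. Over all genes, edgeR's quasi-likelihood test called 4237 of 20405 tested genes higher in mK4 and 3988 lower at a Benjamini-Hochberg adjusted p under 0.05. Of these, 2694 were at least 2-fold higher and 2079 at least 2-fold lower. A total of 12180 genes were not called. Among the called genes, 484 were listed at 0 in every mK3 library and 418 at 0 in every mK4 library. For these genes a fold is given as a lower bound, computed against a floor of 3 counts per library (at most 0.0242 CPM in mK3 and 0.022 CPM in mK4). The bound holds only if a 0 means no more than 3 counts, which is uncertain. Podxl had 65, 0 and 65 counts in the mK3 libraries, and Col8a1 had 184, 0 and 100 in the mK4 libraries. In a fit without any gene at 0 in every library of a line, 2183 genes were at least 2-fold higher and 1606 at least 2-fold lower. When only the 12490 genes with at least 1 CPM in all 6 libraries were tested, which also removes other low genes, 1391 were at least 2-fold higher and 973 at least 2-fold lower.

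Genes of nephrogenesis differed strongly, and not in one direction. Of the fixed nephron progenitor list, which names genes of the cap mesenchyme, 7 of 17 tested members were higher in mK4 and 4 were lower (8 and 6 when adjusted over the list alone). Eya1, a transcriptional co-activator gene needed for kidney formation, rose from 10.1 ± 0.818 to 186 ± 31.1 CPM. Pax2 was at 0 in mK3 and 30.0 ± 4.11 CPM in mK4, at least 1240-fold higher against the floor, and Sall1 was at 0 in mK3 and 10.3 ± 0.16 CPM in mK4, at least 426-fold higher against the floor. Osr1, an early marker of nephron-forming mesenchyme, fell from 11.2 ± 0.779 to 2.25 ± 0.235 CPM. Six2, which maintains nephron progenitors, had 59, 15 and 61 counts in the mK3 libraries (0.338 ± 0.199 CPM) and 0 in mK4, a low level in both lines, and its adjusted p was 0.00921. Cited1, Wt1 and Hoxd11 were too low to be tested. Cited1 had 6, 0 and 0 counts in mK3 and 0, 11 and 0 in mK4, Wt1 had 103, 0 and 45 counts in mK4 and 0 in mK3, and Hoxd11 had 0 in all 6 libraries. Gdnf, the growth factor gene that draws in the ureteric bud, stood at 13.9 ± 0.796 and 7.68 ± 3.02 CPM (adjusted p = 0.0543), and passed in 6 of 15 alternatives, among them without mK4 replicate 1 (adjusted p = 0.00775, range over the alternatives 0.00775 to 0.146). The list as a whole did not stand apart from other genes (camera, adjusted p = 0.468).

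The list of induced mesenchyme and renal vesicle genes, which are switched on as mesenchyme turns into epithelium, was higher in mK4, with 10 of 17 tested members higher and 3 lower (the same counts when adjusted over the list alone) and a median log2 fold change of 2.10 (camera, adjusted p = 0.00868 with a preset correlation; adjusted p = 0.137 with an estimated correlation). Cdh6, a cadherin gene of the renal vesicle, was at 0 in mK3 and 1668 ± 50.5 CPM in mK4. Pax8 rose from 0.616 ± 0.131 to 39.4 ± 3.91 CPM and Ccnd1 from 7.70 ± 0.417 to 27.6 ± 1.12 CPM. Wnt4, the signal that drives the mesenchyme-to-epithelium transition, stood at 0.381 ± 0.387 CPM in mK3 and 12.3 ± 1.03 CPM in mK4 (adjusted p = 0.0202). Its call was lost without mK3 replicate 1 or any mK4 replicate (range over 14 alternatives 0.00175 to 0.0691). Lhx1 had 0, 3 and 0 counts in mK3 and 0.569 ± 0.207 CPM in mK4 (adjusted p = 0.0112). Against the direction of the list, Sfrp2 fell from 195 ± 1.75 to 0.14 ± 0.16 CPM, Papss2 from 2.97 ± 0.576 to 0.662 ± 0.024 CPM, and Jag1 from 9.53 ± 0.745 to 4.46 ± 0.448 CPM.

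Epithelial genes were partly higher in mK4. Of the 32 listed epithelial junction and keratin genes, 18 were high enough to be tested. Of these, 6 were higher and 1 was lower (7 and 1 adjusted over the list alone), with a median log2 fold change of 1.65 (camera, adjusted p = 0.0153; adjusted p = 0.134 with an estimated correlation). The tight-junction gene Cgn rose from 14.8 ± 1.48 to 59.3 ± 7.51 CPM. The protease inhibitor gene Spint1 fell from 3.38 ± 0.938 to 0.063 ± 0.11 CPM (adjusted p = 0.0334). Its call was lost without any library other than mK4 replicate 1 (range over 14 alternatives 0.000492 to 0.0932). The epithelial adhesion genes Cdh1 and Epcam were too low to be tested in either line: Cdh1 had 59, 0 and 59 counts in mK4 and 0 in mK3, and Epcam had 0, 0 and 90 counts in mK3 and 0 in mK4. Among the 11 tested of 24 listed genes of differentiated tubules, 5 were higher and 3 lower (the same adjusted over the list alone; camera, adjusted p = 0.289). The water channel gene Aqp1 rose from 8.43 ± 1.00 to 222 ± 8.49 CPM, and Cdh16, the kidney-specific cadherin gene, was at 0 in mK3 and 84.2 ± 4.41 CPM in mK4. Slc3a1 and Ass1 fell from 14.7 ± 3.62 to 0.19 ± 0.049 CPM and from 67.4 ± 8.31 to 17.7 ± 0.549 CPM. Of the 22 listed ureteric bud and collecting duct genes 14 were tested, with 7 higher and 1 lower (the same adjusted over the list alone) and a median log2 fold change of 1.09 (camera, adjusted p = 0.0271; adjusted p = 0.142 with an estimated correlation). Wfdc2 and Wnt7b were at 0 in mK3 and at 29.4 ± 6.08 and 11.04 ± 2.48 CPM in mK4. Ret, the receptor gene for GDNF, had 14, 180 and 55 counts in mK3 and 0 in mK4 (adjusted p = 0.0188, and 0.0518 without mK3 replicate 3, range over 14 alternatives 7.09e-06 to 0.0539). Of 17 podocyte genes, 3 were higher and 2 lower (the same adjusted over the list alone; camera, adjusted p = 0.44), with Podxl rising from 0.325 ± 0.284 to 59.0 ± 8.49 CPM and Thsd7a falling from 131 ± 11.1 to 3.72 ± 2.37 CPM.

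**Figure D1:**
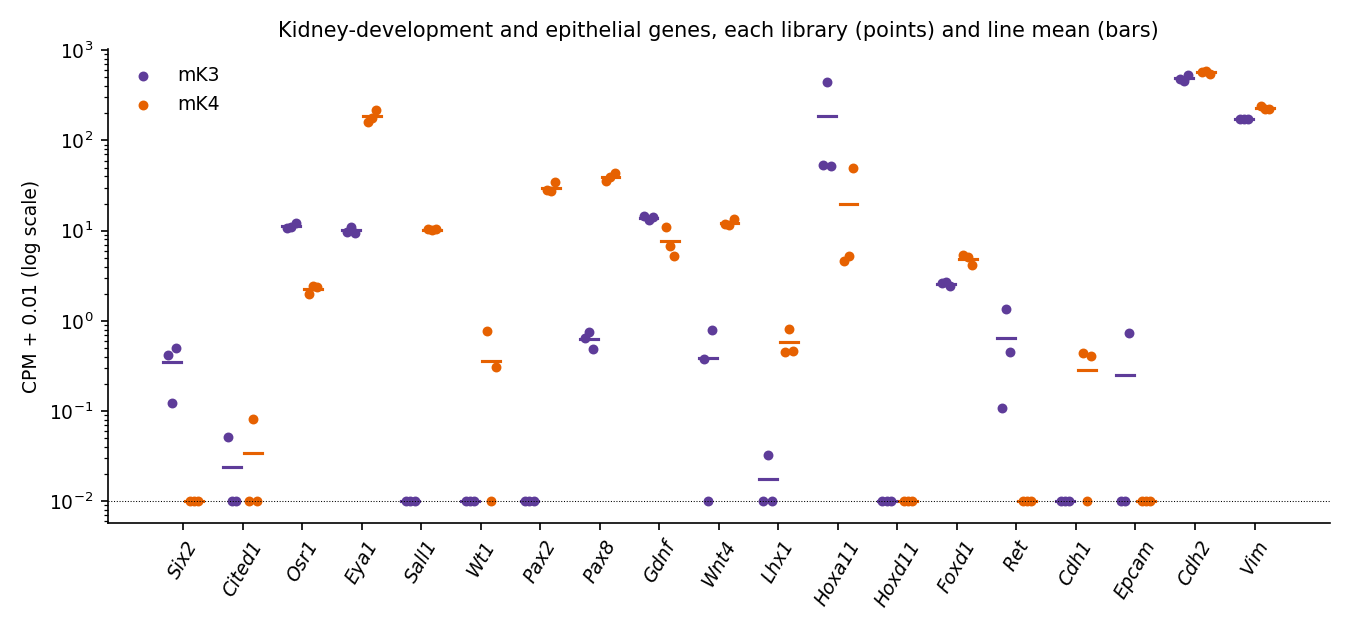
CPM of the 19 genes named in advance in each RNA-seq library, on a logarithmic axis with 0.01 CPM added, where points are libraries, bars are line means and the dotted line marks a count of 0. Pax2 and Sall1 lie at 0 in the 3 mK3 libraries and near 30.0 and 10.3 CPM in mK4, while Cdh2 and Vim are high in both lines.

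Mesenchymal genes were lower in mK4 as a group. Of 28 tested members of the mesenchymal and EMT list, 20 were lower and 4 higher (22 and 5 adjusted over the list alone), with a median log2 fold change of -2.01 (camera, adjusted p = 2.48e-07; adjusted p = 0.119 with an estimated correlation). Col3a1 fell from 707 ± 78.8 to 4.12 ± 0.245 CPM and Postn from 617 ± 37.5 to 14.4 ± 1.12 CPM. The mesenchymal markers Cdh2 and Vim did not follow: Cdh2 stood at 493 ± 36.8 and 569 ± 24.8 CPM (adjusted p = 0.0651, and 0.0119 without TMM scaling, range over 15 alternatives 0.0119 to 0.172), and Vim rose from 172 ± 1.28 to 231 ± 10.8 CPM. The transcription factor genes Twist2 and Zeb1 were also higher in mK4, with log2 fold changes of 0.75 (SE 0.06) and 0.83 (SE 0.08). Of 16 genes of contractile smooth muscle and myofibroblasts, 9 were lower and 1 was higher (the same adjusted over the list alone), with a median of -2.46 (camera, adjusted p = 6.39e-05; adjusted p = 0.119 with an estimated correlation; adjusted p = 0.146 among genes with at least 1 CPM in all libraries, range over 13 alternatives 7.79e-08 to 0.146). Tagln was at 64.7 ± 1.21 CPM in mK3 and 0 in mK4, at least 2941-fold lower against the floor, and Ccn2 fell from 71.1 ± 0.565 to 6.80 ± 0.341 CPM, while Mylk rose from 2.97 ± 0.822 to 10.1 ± 0.92 CPM. Renal stroma genes were lower in 10 of 18 cases and higher in 4 (11 and 5 adjusted over the list alone), with a median of -1.34 (camera, adjusted p = 0.0148; adjusted p = 0.134 with an estimated correlation). Pdgfrb fell from 192 ± 10.9 to 51.2 ± 2.63 CPM and Snai2 from 22.1 ± 2.47 to 1.14 ± 0.143 CPM, both of which are also on the mesenchymal list. Foxd1, the marker of stromal progenitors, rose from 2.56 ± 0.146 to 4.84 ± 0.594 CPM.

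**Figure D2:**
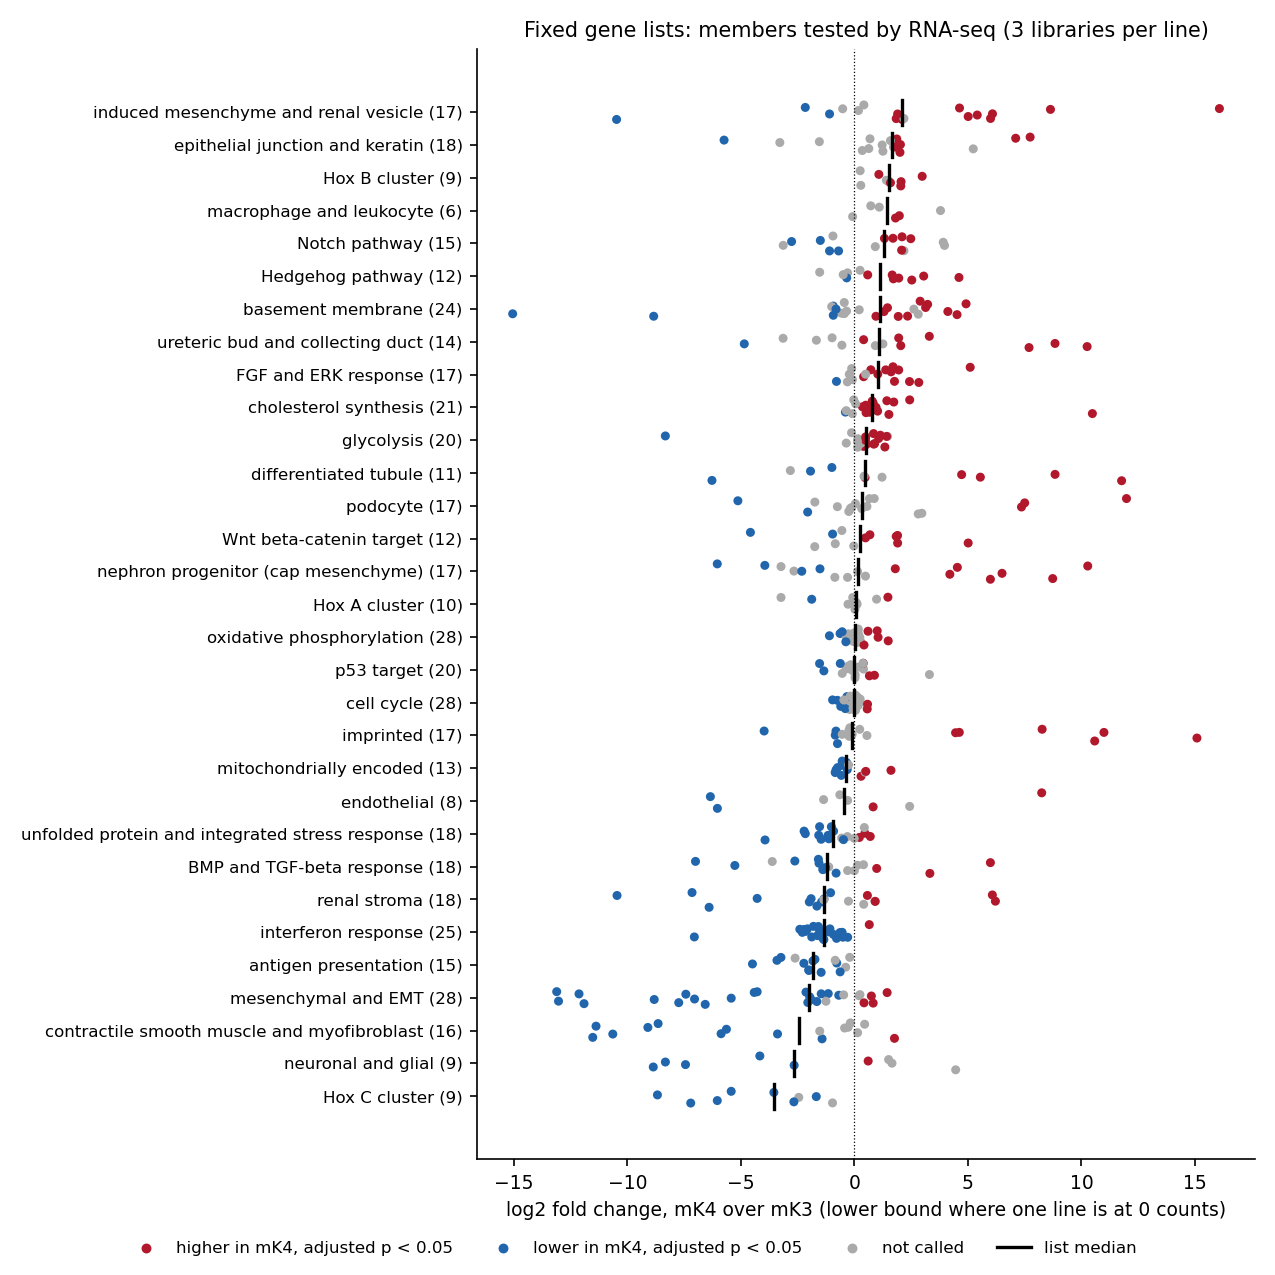
Log2 fold changes (mK4 over mK3) of the tested members of the 31 gene lists with at least 5 tested members, ordered by list median (black bar), with the number of members in parentheses and lower bounds for genes at 0 in one line. Red and blue points passed the test as higher and lower in mK4, and medians run from -3.55 for the Hox C cluster to 2.10 for induced mesenchyme and renal vesicle.

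Several signalling lists moved. Genes that respond to FGF and ERK signalling were higher in mK4, with 11 of 17 higher and 1 lower (12 and 1 adjusted over the list alone) and a median of 1.03 (camera, adjusted p = 0.00743; adjusted p = 0.122 with an estimated correlation). Dusp6, an ERK phosphatase gene, rose from 4.81 ± 0.903 to 34.3 ± 1.78 CPM and Phlda1 from 6.83 ± 0.635 to 20.9 ± 1.18 CPM, while Spry2 fell from 10.5 ± 0.794 to 6.04 ± 0.786 CPM. Of 12 Hedgehog pathway genes, 7 were higher and 1 lower (7 and 2 adjusted over the list alone), with a median of 1.13 (camera, adjusted p = 0.0302; adjusted p = 0.21 with an estimated correlation; adjusted p = 0.092 among genes with at least 1 CPM in all libraries, range over 13 alternatives 5.28e-05 to 0.21). Ptch1, the receptor gene that is itself a pathway target, rose from 16.7 ± 0.381 to 53.1 ± 1.94 CPM and Cdon from 35.2 ± 1.57 to 116 ± 3.62 CPM. BMP and TGF-beta response genes were lower in 9 of 18 cases and higher in 3 (11 and 3 adjusted over the list alone), with a median of -1.20 (camera, adjusted p = 0.0153; adjusted p = 0.142 with an estimated correlation; adjusted p = 0.0559 among genes with at least 1 CPM in all libraries, range over 13 alternatives 1.51e-05 to 0.142). The BMP antagonist gene Grem1 fell from 283 ± 5.97 to 2.21 ± 0.099 CPM and Ltbp2 from 28.5 ± 9.69 to 0.741 ± 0.054 CPM, while Tgfbi rose from 3.12 ± 0.903 to 31.3 ± 2.53 CPM. The Notch pathway had 5 higher and 4 lower of 15 (6 and 4 adjusted over the list alone; camera, adjusted p = 0.425), with Notch2 rising from 552 ± 55.9 to 1794 ± 24.4 CPM and Notch3 falling from 59.8 ± 16.6 to 8.80 ± 0.994 CPM. Of 12 Wnt and beta-catenin targets, 6 were higher and 2 lower (the same adjusted over the list alone; camera, adjusted p = 0.424), Lef1 among the former at 1.76 ± 0.385 and 6.61 ± 1.32 CPM.

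The Hox clusters, whose genes mark position along the body axis, differed by cluster. In the Hox B cluster 6 of 9 tested genes were higher in mK4 and none lower (7 higher adjusted over the list alone), with a median of 1.52 (camera, adjusted p = 0.0061; adjusted p = 0.122 with an estimated correlation). Hoxb13 rose from 0.678 ± 0.101 to 5.37 ± 0.324 CPM and Hoxb6 from 4.67 ± 1.08 to 14.05 ± 0.617 CPM. In the Hox C cluster 7 of 9 were lower and none higher (the same adjusted over the list alone), with a median of -3.55 (camera, adjusted p = 6.39e-05; adjusted p = 0.119 with an estimated correlation). Hoxc13 and Hoxc10 were at 8.98 ± 1.24 and 3.25 ± 0.232 CPM in mK3 and at 0 in mK4. This cluster lies on chromosome 15, whose 690 tested genes had a median log2 fold change of -0.50. In the Hox A cluster 1 of 10 was higher and 1 lower (the same adjusted over the list alone; camera, adjusted p = 0.868, with a median of 0.05 and a mean of -0.27). Hoxa10 fell from 74.4 ± 5.36 to 20.2 ± 2.28 CPM. Hoxa11 varied widely within each line, with 7641, 59478 and 6447 counts in mK3 and 634, 799 and 7374 in mK4 (adjusted p = 0.111, and 0.0384 without mK4 replicate 3, range over 14 alternatives 0.0384 to 0.4). Of the Hox D genes only Hoxd8 was tested, at 0.159 ± 0.023 CPM in mK3 and 0 in mK4.

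Genes of the interferon response were lower in mK4 in 24 of 25 cases, with Ifit2 the exception (the same counts adjusted over the list alone). Their median log2 fold change was -1.35 (camera, adjusted p = 7.33e-11; adjusted p = 0.119 with an estimated correlation). Ifih1, which encodes the RNA sensor MDA5, fell from 189 ± 8.04 to 38.6 ± 2.93 CPM and Oas2 from 204 ± 9.63 to 69.8 ± 2.03 CPM, while Ifit2 rose from 53.9 ± 2.08 to 84.9 ± 6.06 CPM. Antigen presentation genes were lower in 11 of 15 cases and higher in none (the same adjusted over the list alone), with a median of -1.82 (camera, adjusted p = 5.5e-07; adjusted p = 0.119 with an estimated correlation). The class I genes H2-D1 and H2-K1 fell from 163 ± 0.967 to 40.5 ± 2.22 CPM and from 145 ± 8.26 to 43.5 ± 0.972 CPM. They are similar in sequence, so how the counting split their reads is uncertain.

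Metabolic and stress genes also differed. Cholesterol synthesis genes were higher in 16 of 21 cases and lower in 1 (the same adjusted over the list alone), with a median of 0.79 (camera, adjusted p = 6.39e-05; adjusted p = 0.119 with an estimated correlation). Fdps rose from 44.9 ± 2.36 to 243 ± 11.3 CPM and Hsd17b7 from 49.5 ± 2.20 to 100.5 ± 1.49 CPM, while Sc5d fell from 95.2 ± 10.1 to 72.3 ± 4.58 CPM (adjusted p = 0.023, lost without mK3 replicate 2 or 3 or mK4 replicate 1 or 3, range over 15 alternatives 0.00118 to 0.0729). Glycolysis genes were higher in 11 of 20 cases and lower in 1 (13 and 1 adjusted over the list alone), with a median of 0.49 (camera, adjusted p = 0.00318; adjusted p = 0.147 with an estimated correlation). Pgk1 rose from 915 ± 114 to 2321 ± 115 CPM, while the lactate exporter gene Slc16a3 fell from 23.4 ± 1.44 to 0.074 ± 0.086 CPM. Genes of the unfolded protein and integrated stress responses were lower in 11 of 18 cases and higher in 3 (13 and 3 adjusted over the list alone), with a median of -0.96 (camera, adjusted p = 0.00574; adjusted p = 0.147 with an estimated correlation). The cystine transporter gene Slc7a11 fell from 419 ± 18.4 to 27.4 ± 5.46 CPM and the asparagine synthetase gene Asns from 325 ± 35.9 to 118 ± 6.68 CPM, both targets of ATF4, while the endoplasmic reticulum folding gene Pdia4 rose from 158 ± 9.27 to 256 ± 8.49 CPM.

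Those of the remaining lists with at least 5 tested genes did not stand apart from other genes in the camera test. Cell cycle genes had 2 higher, 5 lower and 21 not called (the same adjusted over the list alone; adjusted p = 0.424), with Mki67 at 203 ± 2.09 and 299.8 ± 16.7 CPM and Cdk1 at 98.2 ± 1.79 and 58.4 ± 0.571 CPM. The p53 targets had 3 higher and 3 lower of 20 (2 and 2 adjusted over the list alone; adjusted p = 0.942), and oxidative phosphorylation 5 and 5 of 28 (the same adjusted over the list alone; adjusted p = 0.868). The 13 mitochondrially encoded genes had 3 higher and 8 lower (the same adjusted over the list alone; adjusted p = 0.198), with mt-Nd6 rising and mt-Nd1 falling. Basement membrane genes had 11 higher and 5 lower of 24 (11 and 6 adjusted over the list alone; adjusted p = 0.289). The collagen IV gene Col4a6 rose from 124 ± 20.7 to 2144 ± 35.3 CPM, and Nid1, which encodes the linker protein nidogen, was at 745 ± 53.5 CPM in mK3 and 0 in mK4. Imprinted genes had 6 higher and 4 lower of 17 (6 and 5 adjusted over the list alone; adjusted p = 0.458, with a median of -0.10 and a mean of 2.77). The growth factor gene Igf2 was at 0 in mK3 and 37.0 ± 1.76 CPM in mK4, and Peg3 at 0.009 ± 0.016 and 377 ± 10.1 CPM. Markers of other cell types were sparse. Of 16 endothelial genes 8 were tested, with 2 higher (Cdh5 and Egfl7) and 2 lower (Tek and Kdr; adjusted p = 0.784). Of 16 leukocyte genes 6 were tested, with Cd14 and Coro1a higher (camera, adjusted p = 0.118), the latter with an adjusted p of 0.0611 to 0.0675 without mK3 replicate 1 or 3 or mK4 replicate 3 (range over 14 alternatives 0.00142 to 0.07). Of 16 neuronal and glial genes 9 were tested, with 1 higher and 5 lower, Gap43 and Syt1 among the latter (adjusted p = 0.27). Counts adjusted over the list alone were the same for these 3 lists. Of the skeletal muscle genes only Pax3, which rose from 0.534 ± 0.275 to 23.1 ± 4.51 CPM, and Acta1, at 0.165 ± 0.104 CPM in mK3 and 0 in mK4, were tested, and Acta1 had an adjusted p of 0.0617 without mK3 replicate 1 (range over 14 alternatives 0.00189 to 0.106). Xist, the only tested gene of the sex chromosome list, stood at 0.088 ± 0.058 and 0.616 ± 0.153 CPM (adjusted p = 0.0263), a call lost without mK3 replicate 2 or 3 or any mK4 replicate (range over 13 alternatives 0.00225 to 0.08).

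The count table also held 1196 mature miRNA names, which were fitted on their own. Of 461 tested miRNAs 150 were higher and 162 lower in mK4 (edgeR quasi-likelihood test), 107 and 108 of them by at least 2-fold. Which direction had more calls turned with the method, with 176 higher and 140 lower miRNAs without TMM scaling, 174 and 150 with upper-quartile scaling and 126 and 110, of which 75 and 55 at least 2-fold, with at least 1 CPM in all libraries. miR-143-3p, which is abundant in smooth muscle, fell from 94317 ± 10027 to 629 ± 429 miRNA CPM (log2 fold change -7.23, SE 0.68, adjusted p = 0.000381). miR-214-3p fell from 2033 ± 186 to 10.3 ± 1.04 CPM, miR-199b-5p from 749 ± 75.7 to 3.67 ± 0.479 CPM, miR-148a-5p from 841 ± 43.4 to 0.684 ± 0.798 CPM and miR-676-5p from 287 ± 55.6 to 0.15 ± 0.149 CPM. In the other direction, the clustered miR-182-5p, miR-183-5p and miR-96-5p rose from 1217 ± 157 to 22075 ± 5016 CPM, from 661 ± 48.5 to 11481 ± 1091 CPM and from 26.3 ± 2.16 to 440.1 ± 94.2 CPM. miR-196a-1-3p rose from 0.225 ± 0.23 to 1054 ± 56.1 CPM and miR-181d-5p from 6.90 ± 0.801 to 593 ± 40.0 CPM. miR-467a-5p and miR-467b-5p carried identical counts, fell by 7.23 on the log2 scale and cannot be counted as separate items. The 2250 circular RNA rows had few counts, none of them a count of 1 in any library against 5 to 101 per library with a count of 2, so a 0 may stand for a count of 1. Over rows with at least 10 counts summed over a pair of libraries, log2 values correlated at 0.29 to 0.36 between mK3 replicates. Between mK4 replicates they correlated at 0.15 (1 and 2), -0.04 (1 and 3) and -0.02 (2 and 3). Of 216 tested, 26 were higher and 20 lower, 36 and 14 without TMM scaling, 16 and 18 with at least 1 CPM in all libraries and 17 and 12 with limma-voom. The calls were 11 and 11 without mK3 replicate 1, 16 and 8 without mK3 replicate 2, 14 and 10 without mK3 replicate 3, 23 and 36 without mK4 replicate 1 and 34 and 37 without mK4 replicate 3. The circular RNA novel_circ_0001483 fell from 155730 ± 6239 circRNA CPM to 0.

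**Figure D3:**
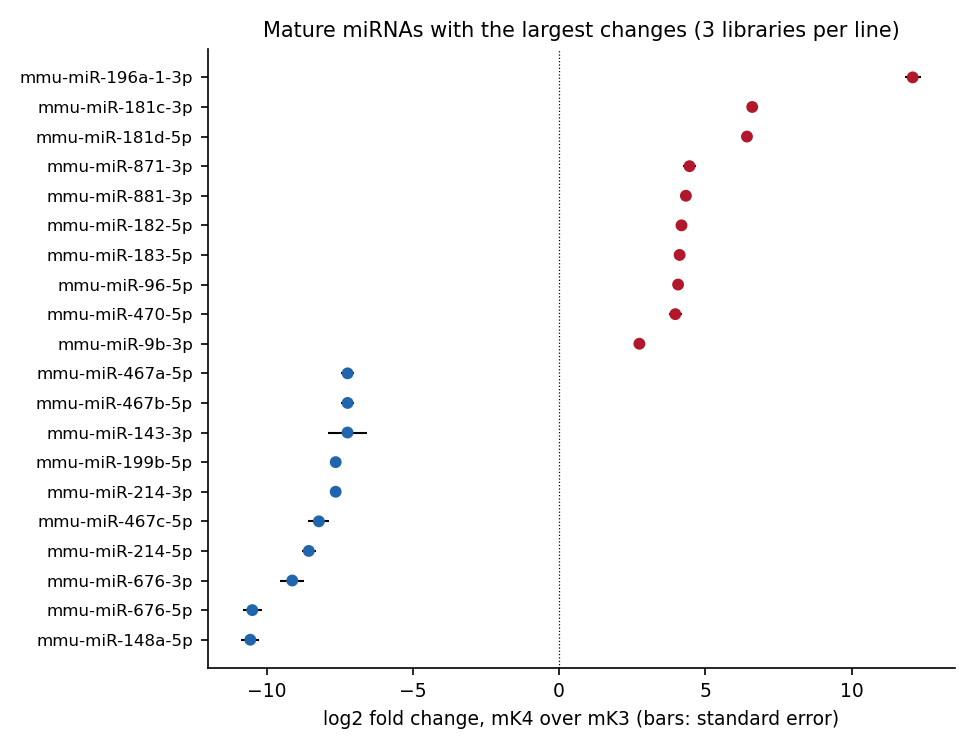
Log2 fold changes (mK4 over mK3, points) with standard errors (bars) of the mature miRNAs with the 10 largest increases and 10 largest decreases that met the expression rule, from 3 libraries per line. Values run from -10.56 for miR-148a-5p to 12.08 for miR-196a-1-3p.

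The second comparison asked where chromatin was open in each line. With 1 ATAC-seq library per line it describes these libraries and has no replicate error. The authors listed 22477 peaks in mK3 and 34710 in mK4 on chromosomes 1 to 19, X and Y, with a median width of 346 and 345 bp. Of the mK3 peaks 16170 (71.9%, exact 95% binomial interval 71.3 to 72.5) overlapped an mK4 peak by at least 1 bp, and of the mK4 peaks 16313 (47.0%, 46.5 to 47.5) overlapped an mK3 peak. With lists of equal length, the shares were 62.1% and 61.7%. Peaks with a partner had a median authors' fold enrichment of 4.68 in mK3 and 5.99 in mK4, against 3.44 and 4.0 for those without. Among the 5 strongest peaks without a partner in mK3 was one at a gene end of Tmem45a (mm10 chromosome 16, 56886067 to 56886617, authors' fold enrichment 10.36), a gene that fell from 312 ± 44.1 to 0.114 ± 0.197 CPM (fitted log2 fold change -11.37), with 0, 52 and 0 counts in the mK4 libraries. Others lay inside Kctd16 (chromosome 18, 40307965 to 40308367) and between genes, 388.1 kb from Epha7 (chromosome 4, 28424367 to 28424923), 16.5 kb from Alyref2 (chromosome 1, 171486651 to 171486974) and 2042.1 kb from Olfm4 (chromosome 14, 82065237 to 82065674). In mK4 the 5 strongest lay inside Abhd2 (chromosome 7, 79336379 to 79337074, 14.21), Stard3nl (chromosome 13, 19364219 to 19364742), Map2k6 (chromosome 11, 110511302 to 110511952) and Cep128 (chromosome 12, 91305473 to 91306176), and 133.5 kb from Adamts5 (chromosome 16, 86034652 to 86035168). Map2k6 rose by 2.10 on the log2 scale and Adamts5 fell by 4.44.

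At the kidney genes named in advance, peaks differed between the lists. Eya1 (chromosome 1, 14168953 to 14311035) held 3 peaks in mK4, 1 of them at a gene end, and none in mK3. Sall1 (chromosome 8, 89027242 to 89044162) held 2 and Pax2 (chromosome 19, 44746601 to 44838269) 2 in mK4 and neither held one in mK3. Pax8 (chromosome 2, 24420551 to 24475599) held 3 peaks in mK4, 1 at a gene end, and 2 in mK3, both inside the gene. Six2 (chromosome 17, 85662736 to 85688254) held 3 peaks in mK3, 2 at gene ends, and none in mK4. Cdh1 held 3 in mK4 and 1 in mK3, all inside the gene, and Ret held 1 in mK4. Vim, Foxd1, Hoxa11 and Cdh2 had gene-end peaks in both lines, as had Gdnf and Cited1, Wnt4 held 1 peak inside the gene in each, and Osr1, Wt1, Lhx1, Hoxd11 and Epcam had none in either. At Hoxa11 the highest -log10 q was 302.7 in mK3 (fold enrichment 5.43) and 175.5 in mK4 (4.82). Gene-end peaks of Cdh2 and Vim in mK3 reached 28.4 and 29.0 at similar fold enrichments (5.51 and 5.55). Why the q values differed so much was not tested. The highest fold enrichment in mK4 was 9.68 at Eya1, 7.85 at Pax8, 6.39 at Sall1 and 6.3 at Cdh1. It was 3.64 at Ret and 3.13 at Pax2, below the mK4 list median of 4.72. At Six2 it was 4.16 in mK3, below the mK3 list median of 4.25. ATAC-seq depth was not compared, so a peak missing from 1 list does not show closed chromatin.

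The third comparison joined the assays. Of 16870 tested genes with coordinates, 688 had a peak within 1 kb of a gene end in mK3 only, 1656 in mK4 only, 8459 in both and 6067 in neither. Genes with a peak in mK3 only had a median log2 fold change of -0.63, and 238 of them were called at least 2-fold lower in mK4 against 44 at least 2-fold higher. Genes with a peak in mK4 only had a median of 0.41, with 440 at least 2-fold higher and 99 at least 2-fold lower. Both medians lay outside those of 10000 random gene lists of the same size matched on mean expression, which ran from -0.11 to 0.18 and from -0.07 to 0.12. The random lists were not matched on chromosome, and chromosome medians ran from -0.50 (chromosome 15) to 0.69 (chromosome 3). How far shifts of whole chromosomes contribute to the class medians was not tested. Genes with a peak in both lines had a median of 0.00. With lists of equal length the median was -0.26 for the mK3 class and 0.57 for the mK4 class. The gene-end class says nothing about genes whose peaks lie farther away, and since the strand of genes was not used, it takes in both ends of a gene.

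**Figure D4:**
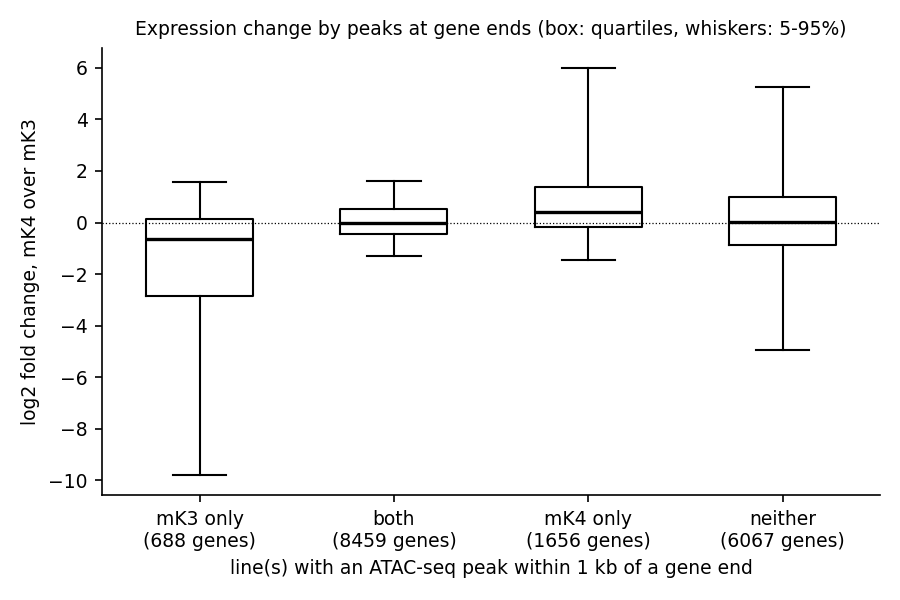
Log2 fold changes (mK4 over mK3) of 16870 tested genes, grouped by which line has an ATAC-seq peak within 1 kb of a gene end, where boxes give quartiles and the median and whiskers the 5th to 95th percentile. The median is -0.63 for peaks in mK3 only, 0.00 for both, 0.41 for mK4 only and 0.00 for neither.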

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

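The pattern of genes at 0 was noticed in the data, and none of the tests given here was chosen after its own result was seen. A total of 39 mK3 peaks and 46 mK4 peaks lay outside chromosomes 1 to 19, X and Y, and were left out of the comparisons. Of these, 30 and 31 lay on the unplaced contig JH584304. No circular RNA had a count of 1 in any library, while 5 to 101 per library had a count of 2, as a cut on low counts would leave, and the labels do not state one.

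Among called genes, 484 were at 0 in every mK3 library and 418 at 0 in every mK4 library. A cut in the counting that set expressed genes to 0 was predicted to leave their ends as open as those of other genes called lower. Of 451 protein-coding genes at 0 in a line, 4.0% had a gene-end peak there, against 38.6% of 451 genes called lower there with counts and matched on the level in the other line, a difference of -34.6 percentage points (95% interval -39.4 to -29.7). The difference overstates the case against a cut, since the matched genes were chosen to have counts in that line. Even in the other line, 23.1% of protein-coding genes at 0 in mK3 and 24.0% of those at 0 in mK4 had a gene-end peak. In the line at 0 the shares were 3.4% and 5.6%. Among all 581 such genes at 0, with or without a match, a peak was present only in the line at 0 for 7 genes and only in the other line for 118 (two-sided exact binomial test, p = 4e-27). Silent genes could give this, but so could low genes set to 0, since all 581 were called lower in that line. Genes called at least 2-fold lower in mK4 also had a peak in mK3 only more often than in mK4 only (238 against 99). For genes at least 2-fold higher the counts were 44 and 440. Whether low counts had been set to 0 stays open, since 70 to 143 protein-coding genes per library had 1 to 3 counts and 89 to 224 had 4 to 6.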

How the results depend on the processing

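The comparisons of miRNAs and circular RNAs, the gene-end class with peaks anywhere in the gene and the fits without genes that jump between replicates and without genes at 0 in a line were chosen after the data were seen. Counts of called genes stayed within 1.5 times of 4237 higher and 3988 lower in every alternative run, and no named gene changed direction in any of its alternatives. Scaling by library totals only moved the median log2 fold change of all genes from 0.024 to 0.131 and the split to 4755 higher and 3380 lower. With at least 1 CPM in all libraries, which tests fewer genes, 1391 genes were at least 2-fold higher and 973 at least 2-fold lower, and 9 of 24 testable lists passed camera in place of 16 of 31, where 4 of the 16 had too few genes left to be tested and 3 lost the call. No list passed with an estimated correlation (0 lists), and 29 passed fry, which does not compare a list with other genes. The estimate was above the preset of 0.01 for some lists that lost the call, such as antigen presentation (0.116). It was below the preset for others, such as ureteric bud (-0.0676), renal stroma (-0.0135) and epithelial junction genes (-0.0111). Higher correlation between genes therefore does not explain every loss. A call lost with an estimated correlation does not show that the genes of a list were correlated, and its cause was not tested. Under fry the endothelial list (adjusted p = 0.00115) went up and the basement membrane list (adjusted p = 0.00142) went down, opposite to camera, and the cause was not tested. Of 137 named genes, 17 lost and 3 gained a call in some alternative.

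Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.019, 0.021 and 0.007 for genes, 0.077, 0.049 and 0.175 for miRNAs and 0.062, 0.052 and -0.008 for circular RNAs, and in none of these classes did every library correlate best with its own number. With the number as a replicate block, 3281 genes were higher and 3129 lower, circular RNA calls were 10 and 9, and Six2 (adjusted p = 0.0727) and Wnt4 (adjusted p = 0.0544) were among the named genes not called. Circular RNA calls were 16 higher with at least 1 CPM and 17 higher and 12 lower with limma-voom, and ran from 11 to 34 higher and 8 to 37 lower without 1 library, and the cause was not tested. The real grouping gave 8225 gene, 312 miRNA and 46 circular RNA calls and 16 lists. Of the 10 splits of the libraries 1, the real one, gave as many, and the others gave at most 0, 0, 0 and 5, but 10 splits are too few for a share under 0.05.

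Requiring a fold enrichment of at least 5 left 7408 mK3 and 15496 mK4 peaks. The overlapping share was 58.9% and 38.1% when 50% of both peaks had to overlap, 77.6% and 49.2% at q below 1e-05, and 62.1% and 61.7% with lists of equal length. With equal lengths the median of genes with a gene-end peak in 1 line only was -0.26 (mK3) and 0.57 (mK4), and for mK4 it was 0.51 with peaks anywhere in the gene, and the cause was not tested. The alternative for normalized values, another pseudocount, did not apply and was not run. Circular RNAs had 6725 to 15019 counts per library, and 33.3% of 9 simulated 4-fold changes in them were recovered.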

Other observations

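The tests of gene families and of chromosome medians against peak counts were chosen after the result was seen. Of 171 gene families defined by symbol, 5 passed camera, none of them with an estimated correlation (adjusted p = 0.941). Guanylate-binding protein genes were lower in mK4 in 9 of 10 cases (adjusted p = 0.00124), among them Gbp3 from 140 ± 4.77 to 40.1 ± 2.39 CPM. Of 12 Serpinb protease inhibitor genes 11 were lower (adjusted p = 0.00235), with Serpinb1a from 35.9 ± 2.63 to 0.317 ± 0.068 CPM. Of 354 zinc finger genes named Zfp 135 were higher and 34 lower (adjusted p = 0.00235), with Zfp974 from 5.01 ± 0.424 to 20.7 ± 0.621 CPM. Of 18 Ifi genes 12 were lower and 1 higher (adjusted p = 0.00235), and of 14 protocadherin beta genes 8 were higher (adjusted p = 0.00867). Family members share sequence, so how their reads were split is uncertain. The family test did not adjust for the chromosome a gene lies on. How far the shifts of whole chromosomes given below contribute to the family results was not tested.

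Mature miRNAs tended to change with the genes that overlap them, where strand was not known. Over 139 host genes with 258 miRNAs, the mean miRNA and host log2 fold changes correlated at r = 0.71 and rho = 0.75 (permutation test, p = 1e-05 for both, the smallest that 100000 permutations can give), and r was 0.64 without the 2 farthest hosts. Genes are not independent replicates. Of 96 hosts of a called miRNA 36 were not called themselves, among them Dnm3 (log2 fold change 0.91, miR-214 -8.10) and Dnm1 (0.25, miR-199b -7.64), and of the other 60, 58 changed in the same direction. As strand was not used, an overlapping gene may lie on the other strand and not be the source of the miRNA. An uncalled host therefore does not show that a miRNA changed apart from its own transcript. Eda, which holds miR-676, had 78.7 CPM in mK3 and 0 in mK4, and Carmn, which holds miR-143 and miR-145a, had 12.04 and 0.461 CPM. Shared transcription is a candidate explanation, and no other was tested.

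Genes of a chromosome tended to shift in the same direction. The median log2 fold change was 0.69 on chromosome 3 and 0.60 on chromosome 7, against -0.50 on chromosome 15 and -0.42 on chromosome 14. Across 20 chromosomes it correlated with the log2 ratio of peak counts (r = 0.85, p = 2e-05, rho = 0.89, p = 1e-05, permutation tests, and r = 0.77 without the 2 farthest), which is consistent with different copy numbers in the lines. Without genes called at least 2-fold changed, the median was 0.39 on chromosome 3, 0.43 on 7, -0.43 on 15 and -0.34 on 14. Strongly changed genes thus did not make all of the shift on these chromosomes. A shift of a whole chromosome also moves more genes past 2-fold in its own direction. The smaller medians therefore cannot show whether separately regulated genes added to the shift. Among the remaining genes, the medians of the first and the second part of each chromosome correlated (permutation tests, r = 0.62, p = 0.0037, rho = 0.73, p = 0.00046, and r = 0.48 without the 2 farthest). As this leaves out the strongly changed genes, it cannot tell how far clusters of them contribute. Gene length or level is argued against by an SD of chromosome medians of 0.281 after correction, against at most 0.055 in 1000 shuffles. The parts differed on chromosome 3 (0.15 and 0.65) and on X (-0.35 and 0.42), the karyotype was not measured, and broad differences in chromatin state stay open.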
